A study of Mus musculus with 10 samples.

How the data were processed

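Total RNA from distal colorectum was measured on 10 Affymetrix arrays, 1 array per sample, with 45101 probe sets each. Per the labels' protocols, RNA was isolated with Trizol, and biotin-labelled cRNA was hybridised. Samples were grouped by the genotype and irradiation that their labels give: unirradiated wild type (n = 2), unirradiated knockout (n = 2), irradiated wild type (n = 3) and irradiated knockout (n = 3). Per the submitters' processing notes, the authors computed the signals with MAS5; a version is not given in the sources used here. The deposited values are on the log2 scale, judged from the values themselves: after raising 2 to each value, the mean trimmed by 2% at each tail was 500 on every array, the usual MAS5 target. They ran from -4.24 to 15.79. No detection calls were used here, and MAS5 spreads dim signals widely, so fold changes of genes that are dim in a group are uncertain. The number of arrays limits the precision.

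Values were used as deposited, without a pseudocount or further normalization. Of the probe sets, 64 were controls, 34945 had 1 gene in the platform annotation, 932 had several and 9160 had none. Symbols were updated by gene ID for 34741 probe sets from a table of the GRCm38.p6 assembly, which was used for names and neighbouring genes only. Each gene was represented by the probe set with the highest mean over the 10 arrays among those with 1 gene, which gave 18193 genes. A gene was tested if its value lay above the array median on at least 2 arrays, which left 12568.

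Differences were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 10 arrays (6 residual degrees of freedom), a variance prior that follows the mean, and Benjamini-Hochberg adjustment at 0.05. The comparisons were irradiated against unirradiated in wild type, in knockout and averaged over both, knockout against wild type without and after irradiation, and the difference of the irradiation effects (interaction). Signed genotype differences are knockout minus wild type. The fit was tested on simulated arrays of 12568 genes with 200 changed: for the genotype difference after irradiation, 55.2%, 89.6% and 92.4% of genes changed by 1, 2 and 3 log2 units were called, with 4 false calls. For irradiation in wild type the shares were 43.3%, 85.1% and 97.0%, and for the interaction 14.9%, 71.6% and 84.8%.

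Gene lists were fixed before the data were examined, as were the comparisons, the rule for named genes and all alternatives except those stated as chosen later. The 30 lists were extracellular matrix, TGF-beta pathway, PDGF family, p53 targets, senescence and secreted factors, proliferation, interferon response, MHC class II presentation, inflammatory cytokines and chemokines, hypoxia response, fatty acid oxidation and ketogenesis, genes next to Pdgfc, sex-linked transcripts, and markers of macrophages, neutrophils, T and NK cells, B and plasma cells, mast cells, endothelium, fibroblasts, smooth muscle, striated muscle, absorptive colonocytes, goblet cells, enteroendocrine cells, crypt stem cells, squamous epithelium, enteric neurons and glia, adipocytes and erythroid cells. Of these, 29 had a measured member. Shifts were tested with camera, two-sided, with a preset correlation of 0.01 between genes and adjustment over the lists of a comparison, and again with an estimated correlation. Camera compares a list with the other genes, and fry, added after seeing the data, tests whether a list moves one way by itself. A list median above or below 0 therefore need not match its camera test.

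Named were Pdgfc; the 8 genes with the largest rise and the 8 with the largest fall past the threshold whose groups did not overlap (no overlap rule for the interaction); the 3 with the smallest p in a direction in which fewer than 3 passed; and up to 4 members of each list past the threshold, or 2 by smallest p where none passed. Genes without an official-style symbol were left out.

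Alternatives were quantile normalization, pseudocounts of 16 and 64 on the linear scale, no filter or a filter on the mean, no trend, array weights, the mean of a gene's probe sets, every probe set, a minimum of 2-fold, the replicate number as a block, fits of only the groups compared, and leaving out each array. When the other array of a pair was left out, the single remaining array was assumed to vary like the other groups. The sex transcript pattern as a covariate was added after seeing the data.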

Results

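Gene expression was measured in the distal colorectum of C57BL/6J mice, about 1 cm above the anus, in animals with intact Pdgfc (wild type) and in animals without it (knockout). Pdgfc encodes a secreted growth factor that signals through the PDGF receptor alpha of fibroblasts and other mesenchymal cells. Some mice of each genotype had received 25 Gy of local γ-irradiation at 2.14 Gy/min, and their tissue was taken 8 weeks later. The series holds 10 arrays of total RNA, each with 45101 probe sets: 2 of unirradiated wild type, 2 of unirradiated knockout, 3 of irradiated wild type and 3 of irradiated knockout. The labels call the replicates biological. The number of arrays limits the precision of every value.

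Array medians lay between 6.64 and 7.18 on the log2 scale, and 0% of probe set values were identical between any 2 arrays. Arrays of a group correlated at r between 0.88 and 0.97 across the genes tested, and irradiated with unirradiated arrays at 0.75 to 0.89; genes are not independent replicates. The log2 difference of the 3′ and 5′ control probe sets, a measure of RNA integrity, moved with irradiation for Gapdh: it lay at -0.54 to -0.35 on the 6 irradiated arrays and at -0.32 to 0.02 on the 4 unirradiated ones. For Actb the arrays overlapped, at 0.44 to 0.58 and 0.35 to 0.66. Xist, the RNA that silences an X chromosome in females, and the Y-linked Kdm5d, Eif2s3y and Uty separated the arrays by sex. Xist lay at 13.48 to 14.18 on 4 arrays and at 6.19 to 7.27 on the other 6, and the mean of the Y-linked genes ran the opposite way. The 4 arrays with the female pattern were all 3 of irradiated wild type and replicate 1 of irradiated knockout. All 4 unirradiated arrays and replicates 2 and 3 of irradiated knockout had the male pattern. In wild type, sex and irradiation therefore ran together, and in knockout they did so in part.

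Pdgfc itself was lower in knockout than in wild type, on both of its probe sets and in both conditions. On the brighter probe set, the log2 signal was 7.25 ± 0.35 (SD, n = 2) in unirradiated wild type and 6.02 ± 0.57 (SD, n = 2) in unirradiated knockout. After irradiation it was 8.66 ± 0.09 (SD, n = 3) in wild type and 6.84 ± 0.50 (SD, n = 3) in knockout. The other probe set gave 7.65 and 5.73 without irradiation and 8.79 and 6.40 after it. In wild type this other probe set had the higher signal, and its genotype differences were larger. On the brighter probe set, the knockout lay at a log2 difference of -1.82 ± 0.32 (SE) after irradiation, a 3.54-fold lower signal. Without irradiation the difference was -1.23 ± 0.40 (SE). Every knockout array lay below every wild-type array of the same condition. As a single gene, Pdgfc had an unadjusted limma p of 2.4e-04 after irradiation and 0.011 without it; over all genes tested, the adjusted p was 0.69 and 0.16. The other probe set, tested with all probe sets, had a difference of -2.38 ± 0.26 (SE) after irradiation (unadjusted p = 3.0e-06, adjusted p = 0.077) and of -1.93 ± 0.32 without it (unadjusted p = 1.1e-04, adjusted p = 0.020). Without replicate 2 of unirradiated wild type or of unirradiated knockout, the unadjusted p of the unirradiated difference on the brighter probe set was 0.078 or 0.094. Where these probe sets lie relative to the deleted part of the gene is not given in the labels, so a remaining signal in knockout does not test the deletion.

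**Figure D1:**
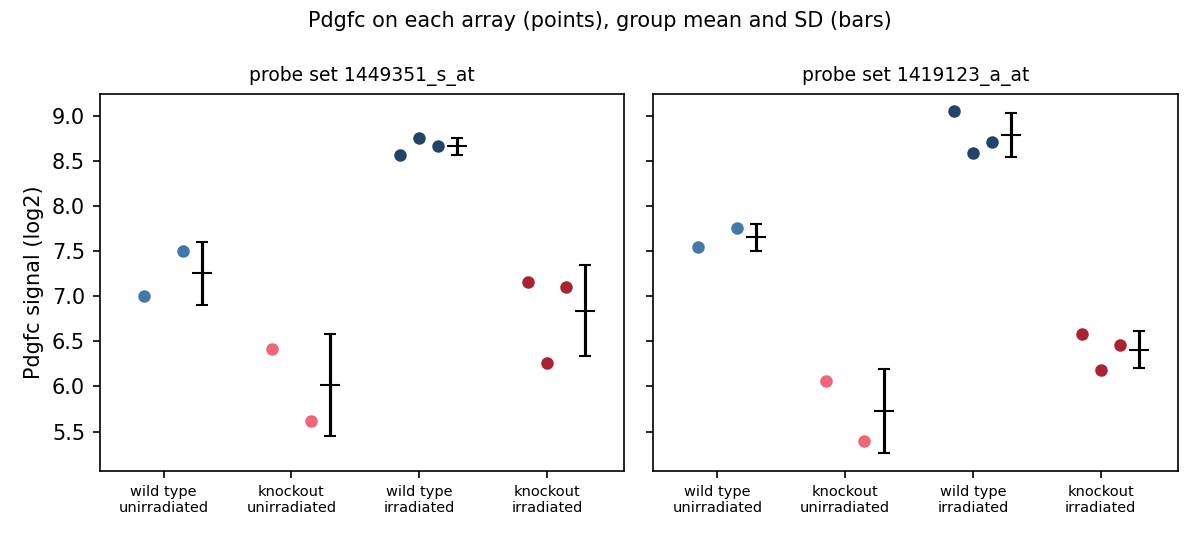
Log2 signal of Pdgfc on each array for both of its probe sets, with points for arrays and bars for the group mean and SD. The irradiated wild-type arrays had means of 8.66 and 8.79, and the irradiated knockout arrays 6.84 and 6.40.

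The first comparison asked what irradiation changed in wild-type tissue. Lists of connective tissue, blood vessel, leukocyte, stratified squamous epithelium and fat transcripts shifted up 8 weeks after irradiation, and that of absorptive colonocytes shifted down. In camera with a preset correlation 18 of 29 lists shifted, and with an estimated correlation 0 did (smallest adjusted p = 0.17). Fry, added after seeing the data, kept 16 of the 18. The Gapdh 3′ to 5′ difference was lower on the irradiated arrays too, at -0.54 to -0.41 against -0.32 and 0.02. Arg1 (arginase, which breaks down arginine in macrophages and other cells) rose by 11.49 ± 0.93 log2 units (SE), S100a9 (a calcium-binding protein of neutrophils and inflamed epithelium) by 9.38 ± 0.85 and Krt14 (a keratin of basal squamous cells) by 8.86 ± 0.80. The other largest rises were in Krtdap, Hp (haptoglobin), Ttn (titin, of striated muscle), the platelet chemokine Ppbp and the retinoic acid-binding protein Crabp2, at 7.88 to 8.46. All 8 lay below the array median in unirradiated wild type, where MAS5 values are imprecise, so the sizes of these rises are uncertain. Among the largest falls, the sodium-proton exchanger Slc9a3 fell by 4.64 ± 0.67, the nucleotide receptor P2ry2 had -3.66, the clock output gene Dbp -2.95, the water channel Aqp8 -2.72, the monocarboxylate transporter Slc16a5 -2.67 and Nxpe4 -2.64. The Y-linked Eif2s3y and Kdm5d made up the rest, at -10.02 and -7.29, and the irradiated wild-type arrays are those with the female pattern.

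Of 33 measured extracellular matrix genes, 30 were higher and 0 lower in irradiated wild type, with a median log2 change of 1.45 (32 adjusted over the list alone). The proteoglycans Lum and Bgn rose by 3.73 ± 0.25 and 2.38 ± 0.17, and the collagen genes Col5a2 and Col1a2 by 2.48 ± 0.18 and 2.08 ± 0.16 (SE, adjusted p = 1.3e-04 to 1.9e-04). Fibroblast markers were higher for 19 of 20 genes (median 2.05; 20 adjusted over the list alone), among them Dcn at 2.40. In the PDGF family 5 of 7 genes were higher and 0 lower (median 1.11; 5 adjusted over the list alone), with Pdgfra at 1.98, Pdgfb at 1.11 and Pdgfc at 1.41 ± 0.36 (adjusted p = 0.021). The TGF-beta pathway had 8 of 23 genes higher and 1 lower (median 0.74; 13 and 3 adjusted over the list alone), with Inhba at 2.84 and Ltbp2 at 3.74. Endothelial markers were higher for 17 of 20 genes (median 1.69; 18 adjusted over the list alone), with Lyve1 at 2.26 and Pecam1 at 1.98. These 5 shifts were past the threshold in camera with a preset correlation, with adjusted p from 7.2e-18 for the matrix to 0.026 for the PDGF family. None was with an estimated correlation, at adjusted p = 0.17 for matrix and fibroblast genes, 0.21 for endothelial markers and 0.29 for the PDGF family and the TGF-beta pathway. The PDGF family shift was also lost without replicate 1 of unirradiated wild type (median 1.11, adjusted p = 0.0505) and with the sex pattern as a covariate chosen after seeing the data (0.94, adjusted p = 0.20).

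Leukocyte marker lists shifted up as well. Macrophage markers were higher for 16 of 17 genes (median 3.15; 16 adjusted over the list alone), with Fcgr3 at 3.36 ± 0.23 and the complement gene C1qb at 3.82 ± 0.29. T and NK cell markers were higher for 12 of 15 genes (median 1.89; 13 adjusted over the list alone), mast cell markers for 7 of 11 (2.90; 9) and neutrophil markers for 4 of 7 (2.43; 5). B and plasma cell markers were higher for 9 of 14 genes and lower for 1 (2.54; 12 and 1), with Ighm at 5.18; Ly6d, at 3.58, is also made by squamous epithelium. Cytokines and chemokines were higher for 18 of 28 genes (2.26; 20), with Ccl8 at 3.0 ± 0.13, Cxcl12 at 2.40 and Cxcl9 at 3.19. Of the senescence and secreted factor list, 15 of 22 genes were higher and 1 lower (2.50; 16 and 1); the cell cycle inhibitor Cdkn1a was the one that fell, by 1.55 ± 0.14. Many of these genes were dim without irradiation. Those above the array median on all 4 unirradiated arrays were 9 of 17 macrophage, 3 of 15 T and NK cell and 3 of 11 mast cell markers. For neutrophils they were 0 of 7, for B and plasma cells 4 of 14 and for cytokines 7 of 28. The sizes of these medians are therefore uncertain. All 7 lists shifted in camera with a preset correlation. With an estimated correlation the adjusted p was 0.17 for macrophage, cytokine and senescence genes and 0.29 for the other 4 lists. With the sex covariate the neutrophil median was 1.60. Interferon response genes were past the threshold for 4 of 28 (Gbp3 1.36, Gbp6 1.52, Bst2 1.08, Ifit3 1.23; 4 adjusted over the list alone) and MHC class II genes for 0 of 11, and neither list shifted (adjusted p = 0.19 and 0.47). Proliferation genes (2 of 32 higher, median 0.24, adjusted p = 0.47) and goblet cell markers (3 of 16 lower and 1 higher, -0.23, adjusted p = 0.061) did not shift either.

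Squamous epithelium markers were higher for 19 of 27 genes (median 5.95; 23 adjusted over the list alone), with Krt6a at 7.50, Krt14 at 8.86 and the transcription factor Trp63 at 6.52. Adipocyte markers were higher for 8 of 15 and lower for 1 (3.23; 9 and 1), with Lpl at 5.45, Adipoq at 7.51 and Car3 at 7.47 ± 0.23. Striated muscle markers were higher for 6 of 24 and lower for 2 (3.81; 8 and 2), with Ryr1 at 5.49 and Neb at 7.52. Absorptive colonocyte markers were lower for 12 of 23 (median -1.27; 14 adjusted over the list alone), with Car1 at -2.13 and Vil1 at -1.33. Fatty acid oxidation genes were lower for 7 of 20 (-0.46; 9), with Acads at -1.13 and Cpt1a at -0.58. Hypoxia response genes were lower for 6 of 19 and higher for 2 (-0.29; 6 and 2), with Car9 at -1.50. These 6 shifts were past the threshold with a preset correlation and not with an estimated one, at adjusted p = 0.17 for colonocytes, 0.70 for striated muscle and 0.29 for the other 4 lists. Without replicate 1 of unirradiated wild type the hypoxia shift was lost (median -0.09, adjusted p = 0.16) and the fatty acid oxidation median was -0.28; without replicate 2 the hypoxia median was -0.54. The striated muscle shift was lost without replicate 1 of irradiated wild type (2.37, adjusted p = 0.26). Replicate 3 showed no striated muscle rise: its list mean was 5.05, against 11.56 and 9.76 in replicates 1 and 2 and 5.41 and 5.51 in unirradiated wild type. Its squamous list mean was 8.61, against 11.62 and 11.33 in replicates 1 and 2 and 4.74 and 5.47 in unirradiated wild type. With the sex covariate the adipocyte median was 0.76 and the colonocyte median -0.75, both still past the threshold with the preset correlation.

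In all, 3028 of 12568 genes were past an adjusted p of 0.05 in limma for wild type, 1980 higher and 1048 lower. The count was 1327 without replicate 1 of unirradiated wild type and 1794 without replicate 2 of irradiated wild type. With the sex pattern as a covariate, chosen after seeing the data and estimated from 1 female array of irradiated knockout, it was 16; the wild-type irradiated arrays were all female and the unirradiated ones all male.

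The second comparison asked the same of knockout tissue, where irradiated and unirradiated arrays of the same sex pattern exist. Lists of extracellular matrix, fibroblast, blood vessel, leukocyte, stratified squamous epithelium, fat, interferon response and MHC class II genes shifted up, and that of absorptive colonocytes shifted down. In camera with a preset correlation 20 of 29 lists shifted, and with an estimated correlation 0 did (smallest adjusted p = 0.091). Fry kept 18 of the 20. The Gapdh 3′ to 5′ difference was -0.47 to -0.35 on the irradiated arrays and -0.23 and -0.22 on the unirradiated ones. Arg1 rose by 11.10 ± 0.93 log2 units (SE). The other largest rises were in Hrnr at 10.93, Rptn at 10.73, Serpinb12 at 10.70, Crct1 at 10.09, Stfa3 at 9.83, and Sprr1b and Tmprss11a at 9.73, of which Crct1 and Sprr1b belong to the squamous epithelium list. All 8 lay below the array median without irradiation. Slc9a3 fell by 3.84 ± 0.67, the epithelial sodium channel subunit Scnn1g by 3.64, the cytochrome P450 gene Cyp2c55 by 3.64 ± 0.51, Dbp fell by 3.52, and the nuclear receptor Nr1i3, near or below the array median in every group, fell by 4.42. Tns4, Sult1c2 and Akr1c19 fell by 3.10, 3.08 and 3.06.

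Extracellular matrix genes were higher for 26 of 33 and lower for 0 (median 1.31; 31 adjusted over the list alone), with Lum at 3.20 ± 0.25 and Col1a2 at 2.01 ± 0.16. Fibroblast markers were higher for 18 of 20 (1.95; 18), endothelial markers for 14 of 20 (1.10; 16) and macrophage markers for 16 of 17 (3.41; 16). Cytokines and chemokines were higher for 20 of 28 (2.72; 22), with Cxcl9 at 6.60 ± 0.28. Senescence and secreted factors were higher for 16 of 22 and lower for 1 (2.47; 18 and 3). Interferon response genes were higher for 19 of 28 (2.0; 23), with Gbp6 at 4.88 ± 0.34 and Ifit2 at 3.66 ± 0.39. MHC class II genes were higher for 8 of 11 (2.52; 8), with H2-Ab1 at 3.15 ± 0.26 and Cd74, the invariant chain, at 2.53 ± 0.22. With an estimated correlation these 8 camera shifts were not past the threshold, at adjusted p = 0.15 for matrix, fibroblast, macrophage, senescence and MHC class II genes, 0.21 for endothelial markers, 0.091 for cytokines and 0.19 for interferon response genes.

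T and NK cell markers were higher for 11 of 15 genes (2.97; 11), B and plasma cell markers for 10 of 14 (2.91; 10 and 1 lower), neutrophil markers for 4 of 7 (3.98; 6) and mast cell markers for 8 of 11 with 1 lower (3.10; 9 and 1). Squamous epithelium markers were higher for 27 of 27 (6.59; 27), with Krt13 at 8.65. Adipocyte markers were higher for 6 of 15 and lower for 1 (1.91; 8 and 2), striated muscle markers for 2 of 24 (2.88; 0), namely Myh2 and Ryr1, and TGF-beta pathway genes for 8 of 23 with 1 lower (0.66; 8 and 2). Absorptive colonocyte markers were lower for 13 of 23 and higher for 0 (-1.24; 13 and 1 higher), goblet cell markers for 4 of 16 with 1 higher (-0.69; 5 and 1) and fatty acid oxidation genes for 5 of 20 (-0.42; 5). The goblet member that rose was Retnlb, an antimicrobial protein, at 5.23. Most T and NK, B and plasma, neutrophil and mast cell markers did not lie above the array median on every unirradiated array. The sizes of their medians are therefore uncertain. Proliferation genes had 2 of 32 higher (0.30; 1), Rrm2 at 1.10 and Rrm1 at 0.74. The PDGF family (2 of 7 higher and 1 lower, median 0.79, adjusted p = 0.13) and hypoxia response genes (2 of 19 higher and 4 lower, -0.24, adjusted p = 0.16) did not shift with the preset correlation; their difference from wild type, by the interaction, was not past the threshold either (adjusted p = 0.59 and 0.22). With an estimated correlation the adjusted p of the 12 lists that shifted was 0.19 for T and NK cells, 0.22 for B cells, 0.24 for neutrophils, 0.21 for mast cells, 0.18 for squamous epithelium, 0.43 for adipocytes, 0.65 for striated muscle and proliferation, 0.28 for the TGF-beta pathway, 0.19 for colonocytes, 0.42 for goblet cells and 0.36 for fatty acid oxidation. Without replicate 1 of unirradiated knockout the proliferation shift turned to -0.02 (adjusted p = 0.62) and the neutrophil median was 7.01. Without replicate 2 of unirradiated knockout the shifts of the TGF-beta pathway (0.68, adjusted p = 0.052) and striated muscle (2.54, adjusted p = 0.0595) were lost, and the medians were 2.33 for neutrophils and 0.63 for proliferation. The proliferation shift was also lost without replicate 2 of irradiated knockout (0.22, adjusted p = 0.22) or replicate 3 of irradiated wild type (0.30, adjusted p = 0.054), and the goblet cell median was -0.46 without replicate 1 of irradiated knockout and with the sex covariate.

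Limma called 2957 genes in knockout, 1763 higher and 1194 lower. The count fell to 1191 and 1291 without replicate 1 or 2 of unirradiated knockout and to 1701 and 1899 without replicate 1 or 3 of irradiated knockout; with the sex covariate it was 1706.

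Averaged over both genotypes, which uses all 10 arrays, 4905 of 12568 genes changed in limma, 2897 higher and 2008 lower. Extracellular matrix genes were higher for 32 of 33 (median log2 change 1.46), fibroblast markers for 19 of 20 (1.91), squamous markers for 27 of 27 (6.03) and macrophage markers for 16 of 17 (3.17), while absorptive colonocyte markers were lower for 16 of 23 and higher for 1 (-1.21). Krt6a rose by 7.05 ± 0.42 (SE), Lum by 3.46 ± 0.18 and C1qb by 3.94 ± 0.21. The chloride exchanger Slc26a3 fell by 2.59 ± 0.48, Slc9a3 by 4.24 ± 0.47 and the transcription factor Tfcp2l1 by 2.54 ± 0.25. The adjusted p with an estimated correlation was 0.18 for matrix, fibroblast, macrophage and colonocyte genes and 0.19 for squamous markers.

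Lists that did not shift on average, even with the preset correlation, included direct p53 targets, with 9 of 26 genes higher and 4 lower (median 0.24, adjusted p = 0.37). Among these, Psrc1 rose by 2.09 ± 0.22 and Plk2 by 1.59 ± 0.20, while Cdkn1a fell by 1.05 ± 0.10 and Gadd45a by 1.22 ± 0.15. Proliferation genes were higher for 6 of 32 (0.25, adjusted p = 0.078). Crypt stem cell markers were higher for 4 of 17 and lower for 2 (-0.08, adjusted p = 0.69); Cd44, which fibroblasts and leukocytes also express, rose by 2.14 and Lgr5 by 0.91 ± 0.26. Smooth muscle markers were higher for 2 of 18 (0.09, adjusted p = 0.58), enteroendocrine markers higher for 1 and lower for 2 of 15 (-0.01, adjusted p = 0.70), and enteric neuron and glia markers higher for 2 and lower for 1 of 16 (0.22, adjusted p = 0.72). Genes next to Pdgfc were higher for 3 of 11 and lower for 1 (0.28, adjusted p = 0.37). Of 6 sex-linked transcripts, 1 was higher and 3 lower (-0.84, adjusted p = 0.57). Erythroid markers had 0 measured members.

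The count over both genotypes lay between 3712 and 5436 when each array was left out, and fell to 818 with the sex covariate. In 100 splits of the arrays within genotype, the real one included, no other split gave more than 183 genes, but another gave 20 shifted lists against the real 21, so shifts called with the preset correlation are a weak measure.

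**Figure D2:**
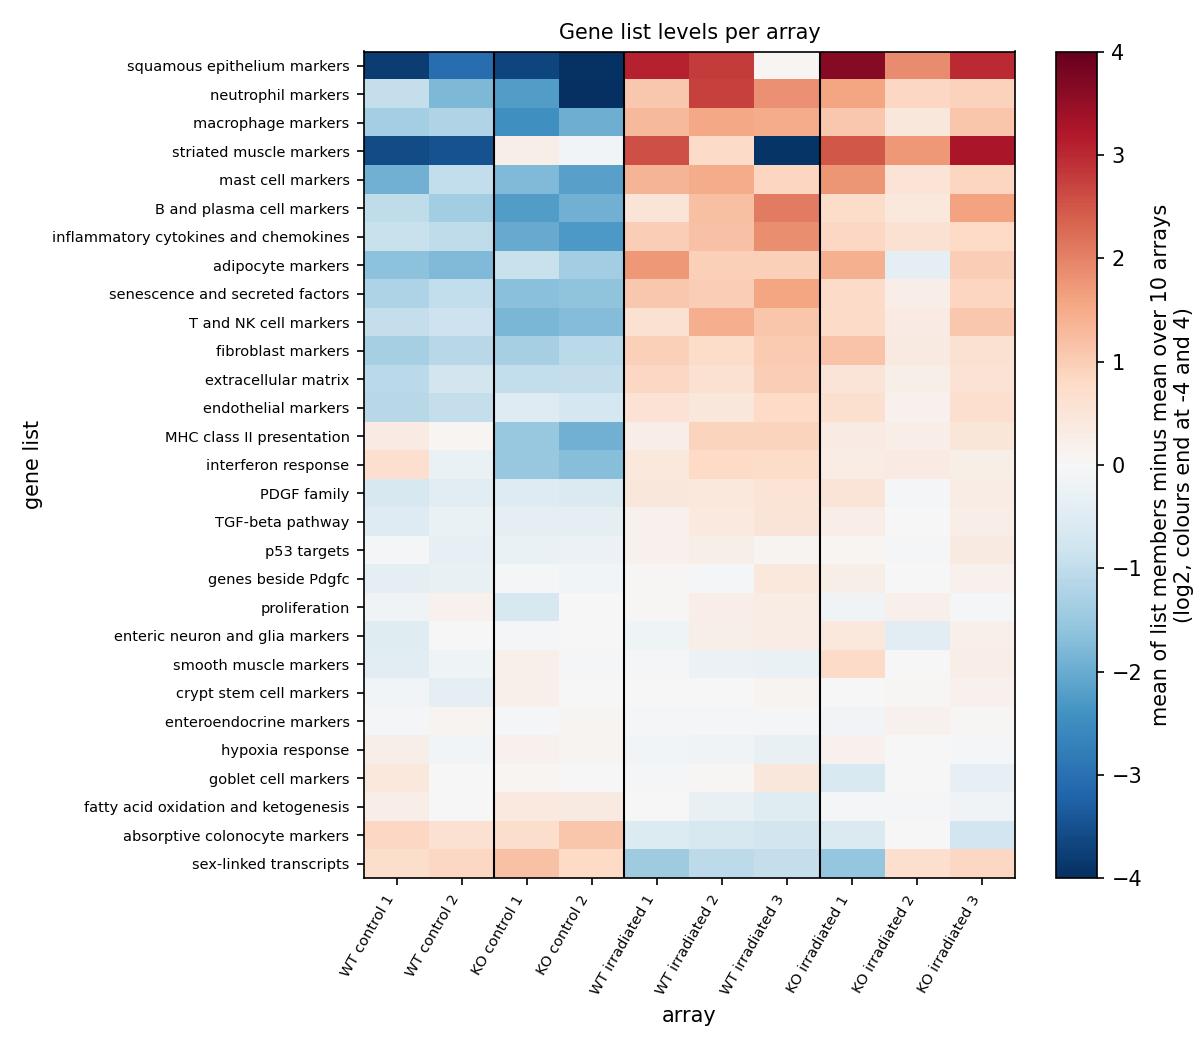
Mean log2 level of each gene list on each array, centred on its mean over the 10 arrays, with colours from -4 to 4 and black lines between the groups. Squamous, macrophage and fibroblast lists were higher on the irradiated arrays, and MHC class II and interferon lists were lowest on the unirradiated knockout arrays.

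How alike the irradiation responses of both genotypes were was asked next; they share no array. Across the 12568 genes, log2 changes in wild type and knockout correlated at r = 0.82 (rho = 0.71); genes are not independent replicates. Of the genes called in wild type, 94.3% changed with the same sign in knockout, where their median change was 0.87 against 1.17 in wild type. These genes were chosen by their wild-type change, which inflates that value, so the smaller knockout median does not show a weaker response. Genes called in knockout had a median size of 1.16 in knockout, and 93.6% of them changed with the same sign in wild type. Both genotypes called 1199 genes as higher, against 278 for independent lists, and 549 as lower, against 99.6; 9 genes were called in opposite directions.

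**Figure D3:**
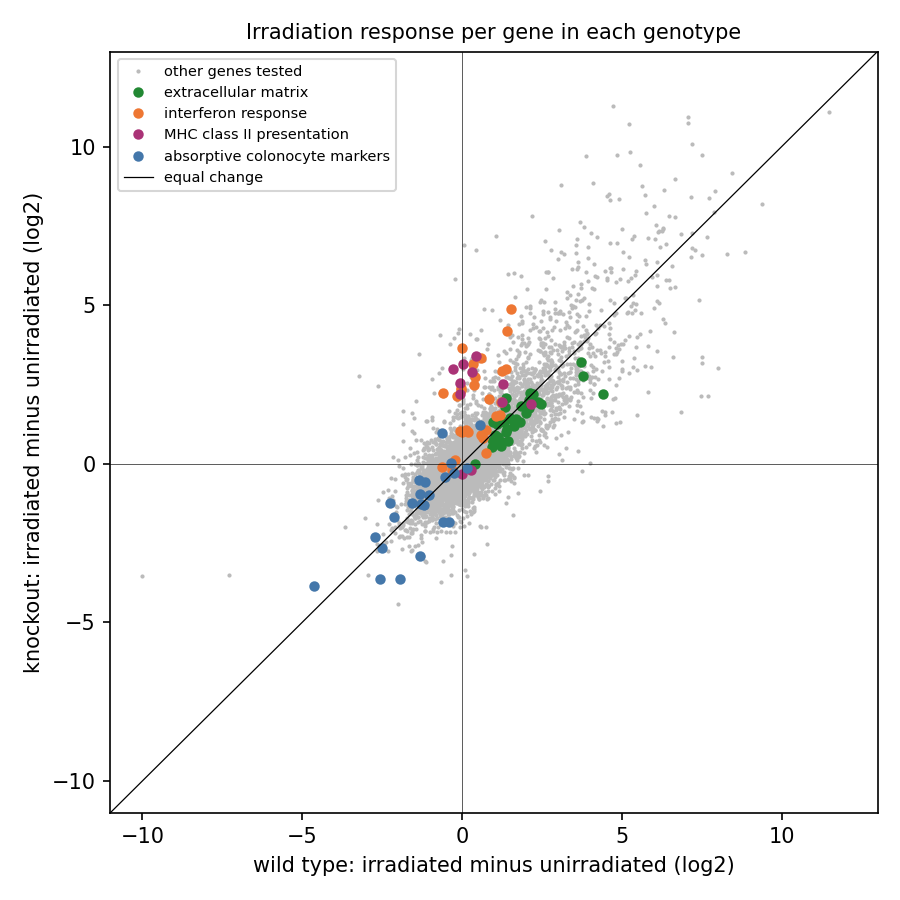
Log2 change after irradiation in wild type (horizontal) and in knockout (vertical) for each gene tested, with 4 lists coloured and a line of equal change. Across genes r was 0.82, and the median of the MHC class II genes was 0.27 in wild type and 2.52 in knockout, above the line.

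The comparison of genotypes without irradiation asked what loss of Pdgfc alone changed. In unirradiated knockout 13 of 28 interferon response genes, 6 of 11 MHC class II genes and 6 of 28 cytokine and chemokine genes were lower than in unirradiated wild type. These 3 lists shifted down in camera with a preset correlation but not with an estimated one (adjusted p = 0.12 for each). The median log2 difference of MHC class II genes was -2.32 (7 lower adjusted over the list alone), and the lower genes included H2-Ab1 at -3.33 ± 0.28 (SE), Cd74 at -2.83 ± 0.24, H2-Eb1 at -2.78 ± 0.18 and the peptide exchange factor H2-DMa at -3.32 ± 0.34, with adjusted p = 2.8e-04 to 0.0023. H2-Ab1 lay at 13.62 ± 0.25 in wild type and 10.29 ± 0.29 in knockout (SD, n = 2 each). That of interferon response genes was -1.57 (23 lower adjusted over the list alone), with the GTPase gene Gbp6 at -3.58 ± 0.38, Ifit2 at -3.76 ± 0.43 and Rsad2 at -2.66 ± 0.33.

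Cytokines and chemokines had a median of -0.67 (14 lower and 1 higher adjusted over the list alone), with Cxcl9 at -4.14 ± 0.30, Ccl5 at -4.45 ± 0.80 and Ccl8 at -1.95 ± 0.14; Cxcl9 and Ccl5 are themselves interferon-induced. The list median was -1.12 without replicate 2 of unirradiated wild type. The largest falls were in Plet1, a surface protein of epithelial and dendritic cells, at -7.24 ± 0.60, the antimicrobial lectin Reg3g at -6.62, the histidine ammonia-lyase gene Hal at -5.60 ± 0.41, Lrg1 at -4.82, St3gal4 at -4.53 and the MHC class I gene H2-Q5 at -4.31. Of the p53 target list 2 of 26 were lower, the interferon-inducible peptide transporter Tap1 at -2.69 and Cdkn1a at -0.99, and the list did not shift (median 0.03, adjusted p = 0.37). Higher in knockout were the carbonic anhydrase gene Car3, abundant in muscle and fat, at 5.31 ± 0.25, the esterase gene Aadac at 4.55, the cytochrome P450 genes Cyp2c55 and Cyp2c65 at 4.22 and 2.45, and Adssl1, Akr1c19, Minar1 and Pm20d1 at 2.74 to 2.91.

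Extracellular matrix genes did not shift between unirradiated genotypes (0 of 33 past the threshold, median -0.01, adjusted p = 0.33). Markers of macrophages (0 of 17 past the threshold and 9 lower adjusted over the list alone, median -0.83), T and NK cells (1 of 15 lower, -0.74), B and plasma cells (1 of 14 lower, -0.46) and neutrophils (1 of 7 lower, -0.66) shifted down in camera, as did senescence and secreted factors (2 of 22 lower, -0.16) and proliferation genes (0 of 32 past the threshold, -0.37). Striated muscle markers (0 of 24 past the threshold, median 3.17), smooth muscle markers (0 of 18, 0.40) and endothelial markers (0 of 20, 0.31) shifted up. With an estimated correlation none of the 12 lists was past the threshold, at adjusted p = 0.12 for interferon, MHC class II and cytokine genes, 0.42 for macrophages, 0.52 for senescence factors, 0.80 for proliferation, neutrophils, T cells, B cells and striated muscle, 0.86 for smooth muscle and 0.87 for endothelium. Most T and NK cell, B and plasma cell, neutrophil and striated muscle markers did not lie above the array median on every unirradiated array. The sizes of their medians are therefore uncertain. Left-out arrays ended several of the 12 shifts. Proliferation was not past the threshold without replicate 1 of unirradiated knockout (-0.03) or replicate 2 of unirradiated wild type (-0.27), and lay at -0.74 without replicate 2 of unirradiated knockout. Neutrophil markers were not without replicate 1 of unirradiated wild type (-0.08) or replicate 2 of unirradiated knockout (-0.24). They lay at -2.70 without replicate 1 of unirradiated knockout, -1.70 without replicate 2 of unirradiated wild type and -1.87 without replicate 2 of irradiated wild type. Without replicate 1 of unirradiated wild type the shifts of B cell (-0.54), smooth muscle (0.24) and endothelial markers (0.30) were lost, and without replicate 1 of unirradiated knockout those of smooth muscle (0.25) and endothelial markers (0.16). The endothelial shift was also lost without replicate 2 of irradiated wild type (0.31, adjusted p = 0.052). B cell markers lay at -0.72 without replicate 2 of unirradiated wild type, and macrophage markers at -0.53 without replicate 1 of unirradiated knockout. The senescence median was -0.56 without replicate 1 of unirradiated wild type, and -0.38 and -0.25 without replicate 1 or 2 of unirradiated knockout. T and NK cell markers lay at -0.49 without replicate 2 of unirradiated wild type and at -1.22 without replicate 2 of unirradiated knockout or of irradiated wild type.

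In total 154 genes differed between unirradiated genotypes in limma, 53 higher and 101 lower in knockout; after quantile normalization 30 were higher and 99 lower. The count was 70 without replicate 2 of unirradiated wild type, 49 and 40 without replicate 1 or 2 of unirradiated knockout, 256 and 98 without replicate 2 or 3 of irradiated knockout, and 100 without replicate 2 of irradiated wild type. Of the 26 genes named for this comparison that were past the threshold, 9 kept their call under every alternative and left-out array.

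The comparison at the centre of the design asked how irradiated knockout tissue differed from irradiated wild-type tissue. No single gene was past the threshold, and lists of extracellular matrix and inflammatory genes had slightly lower medians in knockout. In camera with a preset correlation 18 of 29 lists shifted, and with an estimated correlation 0 did (smallest adjusted p = 0.25). All 3 irradiated wild-type arrays had the female pattern and 1 of the 3 irradiated knockout arrays did, so genotype and sex ran together in part. The genes with the smallest unadjusted p were, on the lower side, the MHC class I-like gene H2-M3 at -1.05 ± 0.14 (SE), the acute-phase gene Saa3 at -2.18 ± 0.30 and the ubiquitin-like gene Ubd at -2.12 ± 0.35. On the higher side they were Cyp2c55 at 2.53 ± 0.46, neuroglobin (Ngb) at 1.82 ± 0.35 and the colonocyte carbonic anhydrase Car1 at 1.52 ± 0.30. None of these 6 was past the threshold (adjusted p = 0.22 to 0.70).

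Extracellular matrix genes had a median log2 difference of -0.33 with 0 of 33 past the threshold, with Tnc at -0.87 ± 0.22 and Bgn at -0.56 ± 0.15. Macrophage markers (0 of 17) had a median of -0.55, cytokines and chemokines (0 of 28) -0.54, senescence and secreted factors (0 of 22) -0.45, goblet cell markers (0 of 16) -0.36, smooth muscle markers (0 of 18) 0.43 and striated muscle markers (0 of 24) 2.74. Adjusted over the list alone, 2 cytokine genes were lower, and 1 smooth and 1 striated muscle gene higher. Camera with a preset correlation called these 7 lists and 11 more; with an estimated correlation the adjusted p was 0.25 for matrix, macrophage, cytokine, senescence and smooth muscle genes and 0.29 for goblet cells and striated muscle, and fry called 0 lists. Without replicate 3 of irradiated wild type the medians were 0.74 for striated muscle, -0.27 for cytokines and -0.22 for goblet cells, and without replicate 1 that of striated muscle was 4.13. Without replicate 1 of irradiated knockout they were 0.23 for smooth muscle and -0.22 for goblet cells, and without replicate 2 they were -0.22 for the matrix and -0.33 for macrophages. One other of the 10 splits of the 6 irradiated arrays also called 18 lists.

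With the sex pattern as a covariate, chosen after seeing the data and estimated from the 1 female array of irradiated knockout, 12 of the 18 lists kept their call and direction, 4 lost the call and 2 turned. Fibroblast markers went from a median of -0.18 to 0.24 (adjusted p = 0.021) and adipocyte markers from -0.40 to 0.24 (adjusted p = 0.66). The senescence median was then -0.23, that of macrophages -0.36, cytokines -0.34, goblet cells -0.60 and smooth muscle 0.95. Without the covariate, the fibroblast call was lost without replicate 2 (-0.02) or 3 (-0.09) of irradiated knockout or replicate 3 of irradiated wild type (-0.09), and the median was -0.37 without replicate 1 of irradiated knockout and -0.32 without replicate 2 of irradiated wild type. The adipocyte call was lost without replicate 2 of irradiated knockout (-0.05) or replicate 1 of irradiated wild type (-0.13), and the median was -0.69 without replicate 1 of irradiated knockout and -0.62 without replicate 3 of irradiated wild type.

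Limma called 0 of 12568 genes after irradiation, with a smallest adjusted p of 0.22, and 500 genes had an unadjusted p under 0.05 where 628 are given by chance. When an array was left out the count lay between 0 and 3. In simulated data for this comparison, 55.2% of genes changed by 1 log2 unit and 89.6% of genes changed by 2 were called. The simulated arrays held 200 changed genes, and the adjustment is stricter where fewer genes change. These shares therefore cannot tell which sizes of change would have been called in the real arrays. Pdgfc itself, at a log2 difference of -1.82 after irradiation, was not called.

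The interaction asked which genes responded to irradiation differently in knockout and wild type. The response was higher in knockout for 5 of 11 MHC class II genes and 3 of 28 interferon response genes, lists whose medians were lower in knockout without irradiation. Both lists shifted in camera with a preset correlation but not with an estimated one (adjusted p = 0.21 and 0.40). H2-Ab1 rose by 3.13 ± 0.37 log2 units more (SE), Cd74 by 2.60 ± 0.30, H2-Eb1 by 2.59 ± 0.24 and H2-DMa by 3.25 ± 0.44. After irradiation Cd74 lay at 13.76 in knockout and 13.99 in wild type, against 11.23 and 14.06 without it. The list medians after irradiation were still lower in knockout, at -0.21 for MHC class II and -0.30 for interferon response genes. Camera called both with a preset but not with an estimated correlation. The MHC class II call was lost without replicate 2 of irradiated wild type (-0.23). Gbp6, Ifit2 and Rsad2 rose by 3.36, 3.66 and 2.80 more, the interferon-induced GTPase genes Iigp1 and Igtp by 3.90 and 3.64, Cxcl9 by 3.41 and Ccl8 by 1.76 ± 0.18. Plet1 (6.06 ± 0.78), Hal (5.62 ± 0.54), Mfsd2a (3.84), Pla2g2a (3.62) and Ly6m (3.51) were the other large differences.

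Car3 showed the opposite sign at -5.32 ± 0.33, from 6.96 to 14.44 in wild type and from 12.27 to 14.42 in knockout. Ttr (-1.55), Slc35e3 (-1.37) and Pdcd4 (-1.36) were the other 3 genes with a lower response in knockout. The interaction median was 2.24 for MHC class II genes (6 higher adjusted over the list alone) and 1.16 for interferon response genes (15 higher). For extracellular matrix genes it was -0.32, with 0 of 33 past the threshold in limma or over the list alone (adjusted p of the list = 0.82 with an estimated correlation). The matrix shift was also lost with the sex covariate (-0.19) and without replicate 1 of unirradiated wild type (-0.16), replicate 2 of unirradiated knockout (-0.23), replicate 2 of irradiated knockout (-0.26) or replicate 1 (-0.27) or 3 (-0.29) of irradiated wild type. The interferon median was 0.70 without replicate 1 of unirradiated wild type. Pdgfc itself had an interaction of -0.59 ± 0.51 (adjusted p = 0.73).

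Limma called 26 genes in the interaction, 22 higher and 4 lower. The count was 14 without either array of unirradiated knockout, 16 and 15 without replicate 1 or 3 of irradiated knockout, 16 with a pseudocount of 64, 10 without a mean-variance trend and 4 with the sex covariate. Of the 20 genes named here that were past the threshold, 0 kept their limma call under every alternative and left-out array. Over all genes tested, 1311 had an unadjusted limma p under 0.05 for the interaction, where 628 are given by chance.

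**Figure D4:**
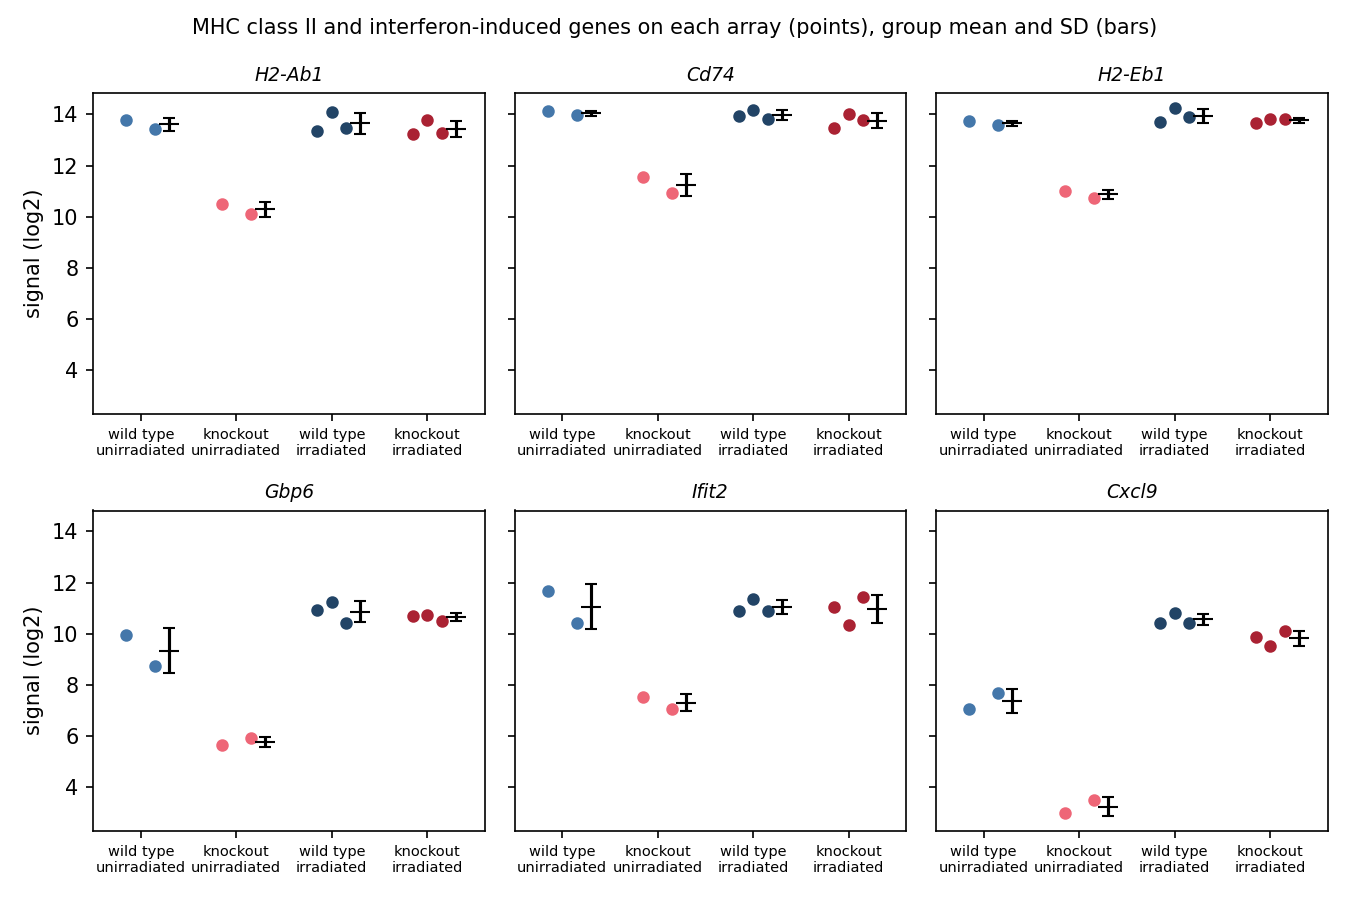
Log2 signal of MHC class II and interferon-induced genes on each array, with points for arrays and bars for the group mean and SD. Unirradiated knockout had the lowest group mean in every panel, with Cd74 at 11.23 against 14.06 in unirradiated wild type and 13.76 in irradiated knockout.

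The last relation set the wild-type irradiation response against the genotype difference after irradiation, which share the irradiated wild-type arrays. Across genes r was -0.06 (rho = -0.25). Simulated arrays with no effect gave a mean r of -0.45, since the shared arrays alone make this relation negative. Those arrays held no irradiation response, and the real response widens the spread of the changes and shrinks r. The 2 values of r can therefore not be compared, and the covariance is the measure to set against the simulation. The covariance was -0.027 against a simulated -0.060, a difference of 0.033. Without replicate 2 of irradiated knockout r was 0.21, so its sign rests on that array.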

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

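The tests of sex, striated muscle, squamous epithelium, leukocytes, scaling, a single array, epithelium share and time of day were chosen only after the results were seen, while the counts over other splits of the arrays were planned.

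The irradiation effect differed between genotypes, by the interaction test, for 26 genes. The differences, knockout minus wild type in log2 units, were 6.06 for Plet1, 5.62 for Hal, 3.90 for Iigp1, 3.84 for Mfsd2a, 3.66 for Ifit2, 3.64 for Igtp, 3.62 for Pla2g2a, 3.51 for Ly6m, 3.41 for Cxcl9, 3.36 for Gbp6, 3.25 for H2-DMa, 3.13 for H2-Ab1, 2.80 for Rsad2, 2.60 for Cd74, 2.59 for H2-Eb1 and 1.76 for Ccl8. They were -5.32 for Car3, -1.55 for Ttr, -1.37 for Slc35e3 and -1.36 for Pdcd4. By list, the median differences were 2.24 for MHC class II presentation, 1.16 for interferon response, 1.13 for squamous epithelium, 0.28 for macrophages, 0.13 for cytokines and chemokines, -0.32 for extracellular matrix, -0.51 for endothelium and -0.79 for adipocytes, none past the threshold with an estimated correlation. The squamous call was lost without replicate 3 of irradiated wild type (0.24), replicate 1 of irradiated knockout (0.73) or replicate 2 of unirradiated wild type (1.19) or knockout (1.65), and its median was 1.75 without replicate 1 of unirradiated wild type. The macrophage call was lost without replicate 1 of unirradiated knockout (0.05), replicate 1 (0.13) or 3 (0.19) of irradiated knockout, replicate 2 of unirradiated wild type (0.19) or replicate 1 of irradiated wild type (0.24). Its median was 0.48 without replicate 1 of unirradiated wild type, 0.63 without replicate 2 of unirradiated knockout and 0.52 without replicate 2 of irradiated knockout. The cytokine median was 0.04 without replicate 1 of irradiated knockout, 0.06, 0.33 and 0.44 without replicate 1, 2 or 3 of irradiated wild type, 0.25 and 0.27 without replicate 1 or 2 of unirradiated wild type and 0.26 without replicate 1 of unirradiated knockout. The matrix call was lost without replicate 1 of unirradiated wild type (-0.16), replicate 2 of unirradiated knockout (-0.23) or of irradiated knockout (-0.26), or replicate 1 (-0.27) or 3 (-0.29) of irradiated wild type, and the interferon median was 0.70 without replicate 1 of unirradiated wild type. The endothelial call was lost without replicate 1 of unirradiated wild type (-0.55) or knockout (-0.47) or replicate 2 of irradiated knockout (-0.35). The adipocyte call was lost without replicate 2 of irradiated knockout (-0.28) or replicate 1 of irradiated wild type (-0.56), and its median was -1.39 without replicate 2 of unirradiated knockout. With the sex covariate the matrix (-0.19), endothelial (-0.41) and adipocyte calls (-0.14) were lost, and the medians were 0.50 for cytokines, 0.56 for macrophages and 2.03 for squamous epithelium. The female transcript pattern was on 4 arrays, all irradiated, although the labels give no sex.

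Connective tissue and leukocyte lists shifted up after irradiation with a preset but not with an estimated correlation, and the irradiated wild-type animals also differed in sex transcripts. Sex alone is argued against as the cause for the wild-type calls as a set: between male irradiated and male unirradiated knockout arrays they moved in the wild-type direction by a median of 0.79 log2 units, and the matrix, fibroblast, macrophage and cytokine lists were each at least 1.17 higher in each male irradiated array than in both male unirradiated ones. For the 397 wild-type calls that did not move that way in both male arrays, sex and irradiation cannot be told apart, since the female minus male difference of 0.25 rests on 1 female array. The other 2631 moved that way in both male arrays, which does not exclude that sex added to the wild-type change of single genes. Striated muscle in the pieces is argued against for matrix and fibroblast genes, because the highest of the 4 list medians between unirradiated genotypes was -0.0084 while striated muscle markers differed by 3.17. Macrophage and cytokine lists were lower in unirradiated knockout, so that comparison cannot decide for them. On 1 array, replicate 3 of irradiated wild type, striated muscle markers lay at 5.05, against 5.41 and 5.51 in unirradiated wild type. Macrophage markers lay at 10.97 there, against 8.11 and 8.26, and cytokines at 9.95, against 7.20 and 7.09. Squamous epithelium, of whose 27 markers 3 lay above the array median on all 4 unirradiated arrays (Krt6a rose from 6.36 to 13.86 in wild type), stays open: over the 6 irradiated arrays its score and the matrix score correlated at r = -0.39 (exact permutation p = 0.447; rho = -0.26, exact permutation p = 0.658; r = -0.34 without the 2 farthest arrays; -0.82 to 0.62 when 1 was left out; 1 relation computed).

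In unirradiated knockout 13 of 28 interferon and 6 of 11 MHC class II genes were lower than in unirradiated wild type, with an adjusted p of 0.12 for each list at an estimated correlation. Scaling of the arrays is argued against as the cause, since the interferon median was -1.58 and the MHC class II median -2.28 after quantile normalization. A single wild-type array standing apart is argued against too, since each wild-type array lay above each knockout array by at least 1.25 log2 units for interferon and 1.60 for MHC class II genes. Fewer leukocytes remain a candidate explanation. The 31 leukocyte markers above the array median in unirradiated wild type had a median of -0.90, with quartiles of -1.74 and -0.68. These overlap the quartiles of MHC class II genes at -3.07 and -0.91. Choosing markers by their level in unirradiated wild type pushes this difference down by itself, so the overlap cannot decide. Over the whole lists the medians were -0.83 for macrophages, -0.74 for T and NK cells, -0.66 for neutrophils and -0.46 for B and plasma cells. The macrophage gene Lyz2 lay at 10.44 in wild type and 9.99 in knockout. The bound for this test was made stricter after its result was seen. Loss of Pdgfc, and differences between litters, cages or microbial exposure, stay open and untested. The unirradiated pieces also differed in tissue content. Striated muscle list means were 9.22 and 8.88 in knockout and 5.41 and 5.51 in wild type. Whether this bears on the interferon and MHC class II genes was not tested, and the interaction uses the same unirradiated arrays.

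Of 9 clock genes that peak with Dbp, 7 were lower after irradiation in wild type and 6 in knockout, and of 4 of the opposite phase 2 and 3 were higher. Whether a lower share of epithelium is the cause stays open. The 9 genes had a median of -1.80 and an upper quartile of -1.57, below the colonocyte marker median of -1.21, while the median of the 4 opposite-phase genes lay above 0. That marker median is no bound for epithelial genes, since Slc9a3 fell more than each of the 9. Nfil3, the opposite-phase gene with the largest rise, was also lower in unirradiated knockout than in unirradiated wild type, at -1.72. Collection at another time of day is a candidate explanation, as the opposite-phase genes had medians of 0.74 in wild type and 1.06 in knockout. The gene list was chosen after Dbp was seen among the largest falls, and an effect of irradiation on the clock was not tested.

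Chance alone is unlikely for the count of irradiation genes averaged over genotypes: 1 of 100 splits within genotype, the real one, gave 4905, and the highest other gave 183. Every other split mixes irradiated and unirradiated arrays, which widens the spread within groups. The splits cannot tell irradiation from sex, which ran with it in wild type. For lists, 1 of 100 splits gave 21, and the highest other gave 20. For genotypes after irradiation the 10 splits of the arrays are too few for a share under 0.05: all 10 gave at least the real count of 0 genes (500 by limma at an unadjusted p under 0.05), the highest other 1, and 2 of 10 gave 18 lists.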

How the results depend on the processing

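The sex covariate, fry and leaving out arrays for Pdgfc and the relations were chosen after seeing the data; the other alternatives given in this part were planned. Counts moved by over 1.5 times under the alternatives given here and no others; the cause was not tested, except that more probe sets, a fold minimum or fewer arrays change what is counted. Testing every probe set gave 4870 irradiation calls in wild type, 5148 in knockout, 8813 on average, 276 between unirradiated genotypes and 49 in the interaction. A 2-fold minimum gave 1810, 1728 and 2057 for irradiation. The interaction count was 16 with a pseudocount of 64 and 10 without a trend. The sex covariate gave 16 in wild type, 1706 in knockout, 818 on average and 4 in the interaction. Among genes past the threshold on average, the responses of both genotypes correlated at r = 0.87. That choice favours genes whose responses go the same way, which raises r by itself. Camera called 97 list shifts, fry called 62, of which 58 were among the 97 in the same direction, and camera with an estimated correlation called 0. For irradiation, fry called 17 lists in wild type, 19 in knockout and 22 on average. It called 3 between unirradiated genotypes, 0 between irradiated ones and 1 in the interaction.

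The replicate number as a block gave 1995 irradiation calls in wild type, 70 between unirradiated genotypes and 3 in the interaction. The numbers do not pair the arrays: 13 same-number pairs correlated at -0.20 to 0.16, and others at -0.25 to 0.24.

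With each array left out, counts ranged over 1327 to 3477 (irradiation in wild type), 1191 to 3601 (knockout), 3712 to 5436 (average), 40 to 256 (unirradiated genotypes), 0 to 3 (irradiated genotypes) and 14 to 35 (interaction). Pdgfc ranged over -1.98 to -1.53 after and -1.63 to -0.83 without irradiation, the relation of both responses over 0.78 to 0.84, that of the wild-type response and the irradiated genotype difference over -0.26 to 0.21, and shifted lists over 90 to 101. Directions turned for proliferation in knockout (-0.016 without replicate 1 of unirradiated knockout, 0.63 without replicate 2) and, with the sex covariate, for fibroblast (0.24) and adipocyte markers (0.24) between irradiated genotypes and for Kdm5d after irradiation in wild type (1.47). The median of squamous markers between irradiated genotypes, 0.61, stayed above 0 (0.19 without replicate 1 of irradiated knockout and 0.12 without replicate 3 of irradiated wild type, adjusted p = 0.91 and 0.54), while camera's direction relative to other genes changed in those 2 fits. Their call was also lost without replicate 1 or 2 of unirradiated wild type (0.61 each) or replicate 3 of irradiated knockout (0.56), and the median was 1.12 without replicate 2 of irradiated knockout and 0.98 without replicate 2 of irradiated wild type, and 1.62 with the sex covariate. Of the named genes past the threshold, 11 of 52 (irradiation in wild type), 18 of 29 (knockout), 15 of 24 (average), 9 of 26 (unirradiated genotypes) and 0 of 20 (interaction) kept their call under every alternative and left-out array. MAS5 signals near background limit the sizes of changes of dim genes.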

Other observations

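The clock gene list, the neighbours of Pdgfc by position and the single-array marker values were chosen after the results were seen.

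Transcripts of the circadian clock were among those changed after irradiation. Averaged over genotypes, 8 of 9 genes that peak with the clock output gene Dbp were lower: Dbp at -3.23 ± 0.38 log2 units (SE), Ciart at -2.48, Per3 at -2.13, Per2 at -1.91, Nr1d2 at -1.80, Tef at -1.77, Nr1d1 at -1.57 and Per1 at -1.05, while Hlf had -0.32 and was not past the threshold. Of 4 genes of the opposite phase, Nfil3 rose by 3.27, Arntl, a core activator of the clock, by 1.20 ± 0.14 and Npas2 by 0.60, and Clock had 0.11, not past the threshold. In wild type alone 7 of the 9 were lower and 2 of the 4 higher, and in knockout 6 and 3. With the sex covariate Ciart, Per2, Per1 and Npas2 lost their call on average (-1.76, -0.88, -0.52 and 0.85). Nr1d1 lost it without replicate 1 of unirradiated knockout (-1.43), and Npas2 without any 1 unirradiated array or replicate 1 or 3 of irradiated wild type (0.52 to 0.68). None of the 13 genes had a genotype-dependent response past the threshold.

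Replicate 3 of irradiated wild type differed from the other 2 over whole lists. Its mean was 5.05 for striated muscle markers, against 11.56 and 9.76, and 8.61 for squamous markers, against 11.62 and 11.33. Krt1, a keratin of cornifying layers, lay at 2.65 in replicate 3 and at 13.05 and 11.12 in replicates 1 and 2, and the fast myosin gene Myh1 at 2.04 against 12.23 and 9.91. The basal keratin gene Krt14 lay at 13.57, beside 13.31 and 14.39. In unirradiated tissue, Myh1 lay at 3.77 and 2.98 in wild type and 11.83 and 10.62 in knockout.

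The genes that differed between unirradiated genotypes were followed after irradiation. The 101 genes lower in unirradiated knockout had a median difference of -2.32 without and -0.07 after irradiation, where 64 still lay below 0, and the 53 higher genes had 1.36 and 0.06, with 33 above 0. Across genes the genotype differences without and after irradiation correlated at r = 0.23. All 26 interaction genes were among the 154 as 22 lower and 4 higher. The interaction contains the unirradiated difference with its sign turned, and the 154 were chosen on that difference, so neither the overlap nor the smaller medians test whether the genotypes became alike; leaving out an array moved the interaction count to between 14 and 35.

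Of 59 tested genes among the 50 on each side of Pdgfc on its chromosome, limma called 0 between genotypes in either condition. Of the 59, 14 had an unadjusted p under 0.05 without irradiation and 3 after it. Among all 12568 genes tested, 2082 and 500 did.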
